A study of Homo sapiens with 11 samples.

How the data were processed

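The series holds RNA sequencing of 11 metastatic melanoma biopsies from human patients, each an independent biopsy and all in one group, with no control samples. Per the labels' protocols, 50000 live cells per biopsy were sorted by flow cytometry with a dead cell dye, polyadenylated RNA was captured on oligo-dT beads, cDNA was amplified with a kit that does not mark strand, and libraries were made by tagmentation. The sort took live cells of every type, so a library can mix tumor, immune and stromal cells in any share. Biopsies are numbered 1 to 11 in the order of the series. The numbers carry no other meaning.

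The authors deposited one gene table per biopsy with 58051 genes. Per the file headers, each table gives the gene length, an effective length, an expected count, TPM (transcript abundance scaled to a fixed library total) and FPKM (fragments scaled by gene length and library total). The expected counts in the deposited tables are estimates that need not be whole, because reads that fit several transcripts are divided among them. The deposited TPM and FPKM values are scaled by effective gene length and by the library's own total. RSEM and Picard are the tools and GRCh38 the genome build per the submitters' processing notes, which give no versions. The aligner and the gene annotation are not given in the sources used here. FPKM was not used. Gene names and coordinates come from GENCODE release 29 on GRCh38, which named 57447 of the 58051 genes, including all 202 genes of the fixed lists.

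Total expected counts ran from 9046339 to 32515256 per biopsy. Intervals on single counts are exact 95% Poisson intervals and cover counting error only, since reads amplified without molecular identifiers are not independent molecules. The mean fragment length of a library was taken as the median of length minus effective length over genes longer than 2000 bases. It separated the libraries at 200 bases into 6 with shorter and 5 with longer fragments. The labels give no batch, so this split is a technical one seen in the files, and it was chosen after the data were examined. No pair of biopsies was near identical, with correlations across genes from 0.585 to 0.923.

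Before the data were examined, 28 gene lists of 6 to 10 genes were fixed: NK cell, T cell, CD8 T cell, regulatory T cell, cytotoxic effector, B cell, plasma cell, cDC1 (type 1 conventional dendritic cell), cDC2, mature dendritic cell, plasmacytoid dendritic cell, macrophage and monocyte, neutrophil, mast cell, melanocyte lineage, dedifferentiated melanoma, fibroblast, endothelial, keratinocyte, erythroid, hepatocyte, interferon gamma response, antigen presentation class II, checkpoint receptor and ligand, proliferation, hypoxia and glycolysis, stress and dissociation, and housekeeping. No gene is in more than 1 list. A list score is the mean, over members with a TPM of at least 1 in at least 2 biopsies, of the z-score of log2(TPM + 1) across the 11 biopsies. Several NK cell list genes (KLRD1, KLRC1, FGFBP2, S1PR5, KIR2DL4) are also expressed by cytotoxic T cells, and IRF8 and CADM1 of the cDC1 list by other cells, so a score is not a cell count. Fixed choices also covered the tests, the threshold (adjusted p under 0.05) and the rule for named genes. That rule names FLT3LG, FLT3, any member of the NK cell, T cell, B cell and cDC1 lists, the members with the highest and lowest association of every other list, and up to 10 genes per direction past the threshold in the scan. Other list members named for their level were chosen after their values were seen.

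Relations across biopsies are Pearson r and Spearman rho with two-sided permutation tests (100000 resamples for 10 or more biopsies, exact enumeration for fewer), with Benjamini-Hochberg adjustment within each family: 28 lists with FLT3LG, 27 lists with the cDC1 score, and 15 varying cytokines of 16 with the cDC1 score. An adjustment over the 4 main lists alone was added after the p-values had been seen. Each r was repeated without the 2 biopsies farthest from the median of the list score or gene. Differences between 2 values of r were tested exactly by swapping the list scores within biopsies (2048 swaps). Partial correlations given the fragment length class and r within the 6 short-fragment biopsies were added after the data were examined. No r was taken over fewer than 6 biopsies, which leaves out the 5 long-fragment ones.

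For the scan of all genes, expected counts were rounded to whole numbers and fitted with edgeR 4.0.16 (quasi-likelihood test, TMM, robust) in R 4.3.3, with FLT3LG as log2(TPM + 1) scaled to an SD of 1 as covariate. The filter filterByExpr was given the design matrix and a minimum count of 10, which left 17144 genes. FLT3LG itself was left out. limma 3.58.1 and DESeq2 1.42.0 served as alternatives, and limma's camera tested the lists with a preset inter-gene correlation of 0.01 and with an estimated one. The other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Other alternatives were another pseudocount (0.1), TMM log2 CPM, unscaled scores, unfiltered members, rank correlation, adjustment for PTPRC or the total count, RLE size factors, no filter on counts, and each biopsy left out. Added alternatives were the number of detected genes, leaving out the 2 biopsies with the highest mitochondrial share, TPM over nuclear genes, and FLT3LG with its overlapping read-through genes.

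The relation test was tested on simulated data: 4.0% of 400 unrelated pairs passed an unadjusted p of 0.05, and 99.0% of 200 pairs with a true r of 0.9 did. The simulated values were normally distributed. Power at a smaller r, or after adjustment within a family, was not simulated. In the simulated scan each gene had its own dispersion estimated from the biopsies (median 2.7). There the test recovered 0 of 100 genes changed by 1 and 1 of 100 changed by 2 on the log2 scale per SD. At a dispersion of 0.2 for every gene it recovered 80 and 100 of 100. The scan could therefore miss most associations of up to 2 on the log2 scale per SD in these biopsies, and larger ones were not simulated.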

Results

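RNA was sequenced from live cells sorted from 11 independent metastatic melanoma biopsies, all in one group. The series asks, by its title, about FLT3LG made by lymphocytes in tumors. FLT3LG encodes the ligand of the receptor FLT3, a growth factor for dendritic cells. With one group and no controls, the comparisons are relations between expression levels across biopsies. Total expected counts ran from 9046339 to 32515256 per biopsy, with a median of 15399517. Apart from those of camera, p-values rest on the spread between these biopsies. Camera compares the genes of a list with the other genes. With the preset inter-gene correlation, its p-values do not rest on the spread between biopsies alone.

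The libraries differed in a technical measure. Mean fragment length was 178.1 to 192.9 bases in biopsies 1, 2, 3, 4, 6 and 7 and 223.3 to 240.5 bases in biopsies 5, 8, 9, 10 and 11. The 6 short-fragment libraries detected 8829 ± 2784 genes at a TPM of at least 1 (SD, n = 6), and the 5 long-fragment libraries 16159 ± 1357 (SD, n = 5; exact permutation p = 0.0043, two-sided). The mean total count of the first class was 1.004 times that of the second, with single libraries from 9046339 to 32515256 in the first and from 13265204 to 27932574 in the second. Mitochondrial transcripts took 27.5% ± 20.2 of the counts in the first class and 7.66% ± 2.19 in the second (exact permutation p = 0.028), with 46.3% in biopsy 6 and 58.8% in biopsy 7.

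**Figure D1:**
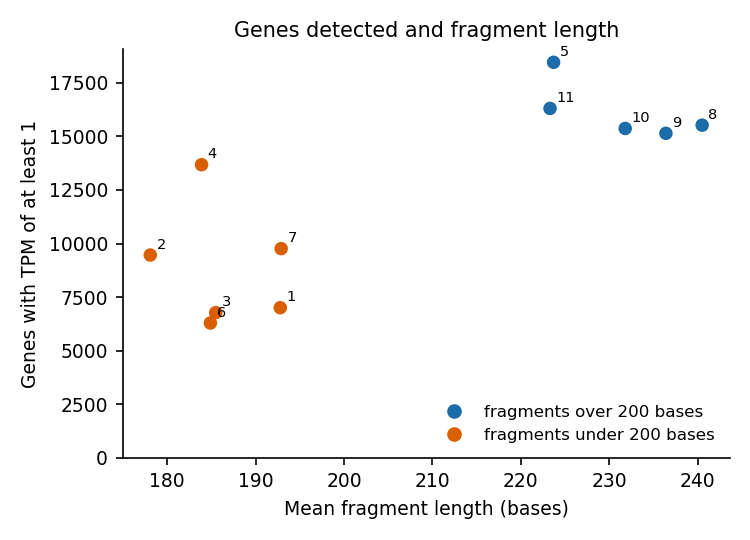
Number of genes with a TPM of at least 1 (vertical axis) against mean fragment length in bases (horizontal axis), one numbered point per biopsy. The 5 libraries above 200 bases detected 15142 to 18457 genes and the 6 below it 6291 to 13677.

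Levels of cell type marker genes differed widely between the biopsies. CD3E, a subunit of the T cell receptor complex, averaged a TPM of 388 ± 297 (SD, n = 11) and ran from 0.77 in biopsy 4 to 867 in biopsy 1. In biopsy 3, CD3E was 580 while CD3G, also of the T cell list, was 1.08, so single markers do not measure the share of a cell type. MS4A1, which encodes the B cell surface protein CD20, ran from 0 to 669 and was highest in biopsies 2 and 3. PMEL, a pigment granule protein of melanocytes, reached 5838 in biopsy 4 and 877 in biopsy 9 and was listed at 0 in biopsies 1 and 2. C1QB, a complement gene of macrophages, was 424 in biopsy 9 and at most 61.8 in the others. KLRD1, a receptor chain of NK cells and cytotoxic T cells, averaged 105 ± 170, with a median of 54.84. Its highest value was 592 in biopsy 3, where the 7 other NK cell list genes were at 0. The cDC1 marker genes were scarce: CLEC9A and XCR1 each reached a TPM of 1 in 2 of 11 biopsies, while IRF8 (67.6 ± 64.3) and CADM1 (55.4 ± 68.2) were abundant. PTPRC, which encodes the leukocyte protein CD45, ran from 22.93 in biopsy 4 to 1127 in biopsy 8.

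**Figure D2:**
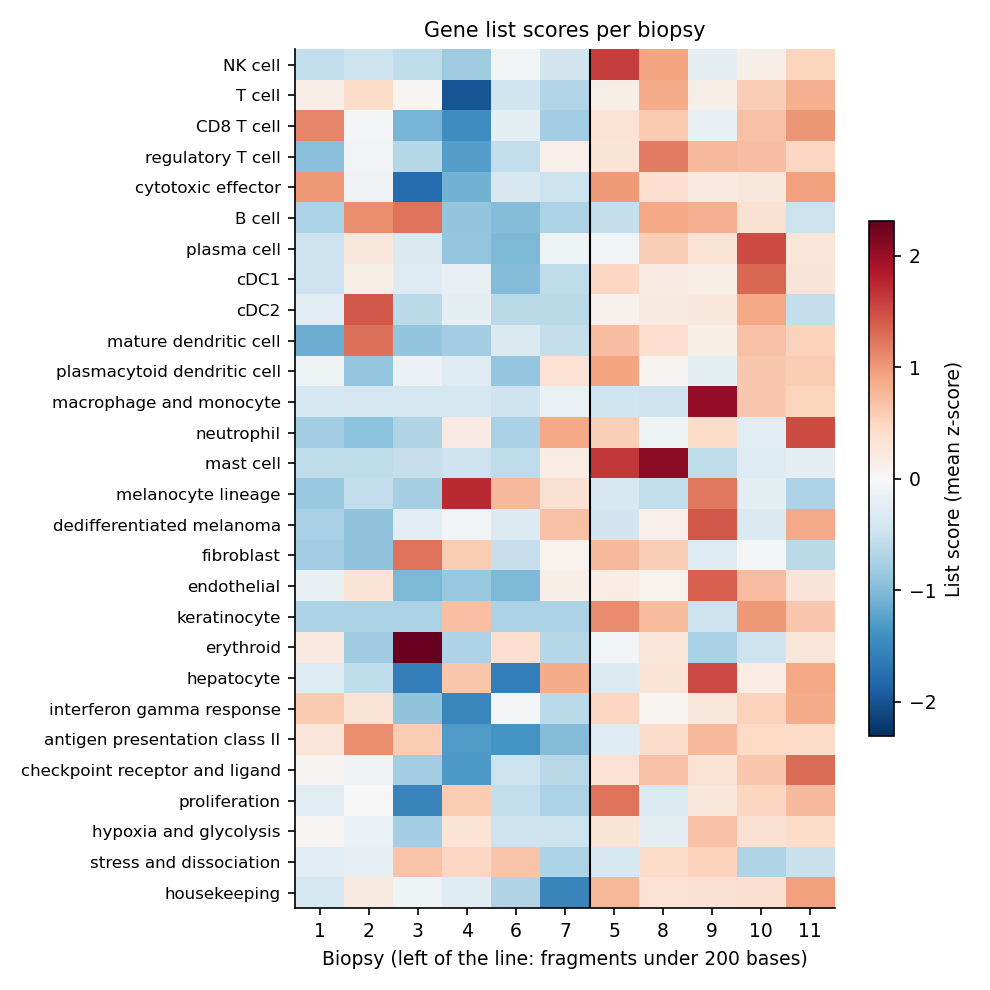
Scores of the 28 gene lists (rows; mean z-score, color scale) in each biopsy (columns), with the 6 short-fragment biopsies left of the line. The macrophage and monocyte score is highest in biopsy 9 and the melanocyte lineage score in biopsy 4, while the T cell score is lowest in biopsy 4.

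FLT3LG (ENSG00000090554, GRCh38 chromosome 19, 49474207 to 49486231, plus strand, protein coding) was low in all biopsies. Its TPM averaged 8.82 ± 9.67 (SD, n = 11), with a median of 7.11 and a range from 0.11 in biopsy 1 to 33.07 in biopsy 8. The expected counts behind these values were 1 (95% Poisson interval 0.03 to 5.57) in biopsy 1, 5 (1.62 to 11.67) in biopsy 7 and 241 (211.53 to 273.43) in biopsy 8. FLT3LG was 15.56 ± 10.78 in the 5 long-fragment biopsies and 3.21 ± 3.24 in the 6 short-fragment ones, a difference of 2.16 in mean log2(TPM + 1) (exact permutation p = 0.015). Read-through genes that join FLT3LG to RPL13A and to ALDH16A1 overlap it, so the division of reads among them is uncertain. Each also overlaps its other partner, so its reads may come from RPL13A or ALDH16A1 rather than FLT3LG. With the TPM of the read-through genes added, biopsy 2 moved from rank 8 to rank 1, the mean of the short-fragment biopsies was 10.03 against 15.77, and the difference between the classes was 1.18 (exact permutation p = 0.180). FLT3 (ENSG00000122025, chromosome 13, 28003274 to 28100592), the receptor of FLT3LG on dendritic cells and progenitors, had 0 counts in the 6 short-fragment biopsies and a TPM of 0.53 to 2.67 in the 5 others. A count of 0 allows up to 3 counts (one-sided 95% Poisson limit). The biopsies thus fall into 2 clusters on FLT3, with no variation in one and 5 biopsies in the other. A pooled r with FLT3LG would largely restate the difference between the classes. Given the class, r was 0.28 (permutation p = 0.429), where all the variation in FLT3 lies in the 5 long-fragment biopsies.

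**Figure D3:**
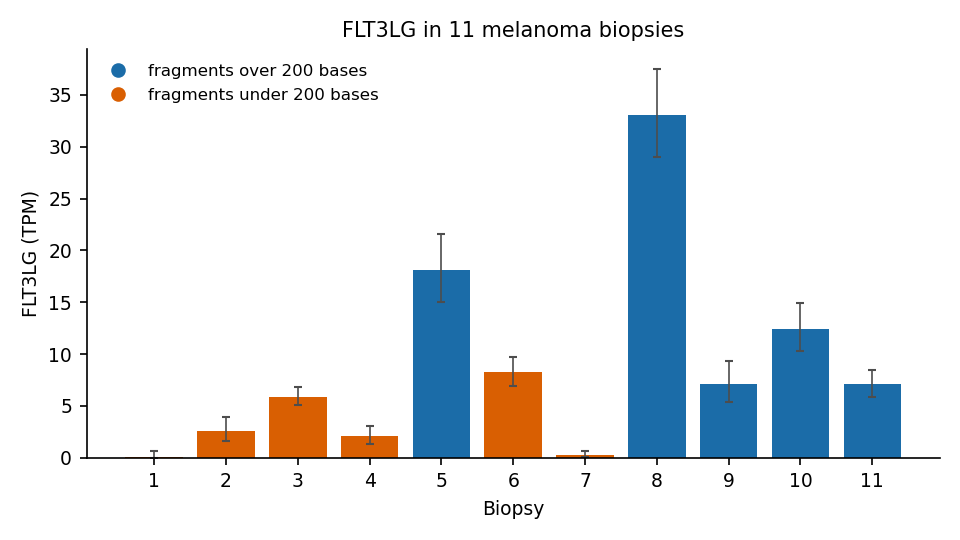
FLT3LG TPM per biopsy (bars, axis from 0) with exact 95% Poisson intervals scaled from the expected counts, which cover counting error only. Biopsy 8 is highest at 33.07, and biopsies 1 and 7 are at 0.11 and 0.3.

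Among the 4 lists the title and the biology of FLT3LG point to, the NK cell score had the closest relation with FLT3LG (r = 0.75, permutation p = 0.0073; rho = 0.82, p = 0.0034; n = 11). The adjusted p was 0.204 over 28 lists and 0.029 over the 4 lists alone, an adjustment added after the p-values had been seen. KLRF1 (r = 0.72), NCR1 (0.71), SH2D1B (0.67) and KLRD1 (0.66), receptors and signaling proteins of NK cells, were the members closest to FLT3LG, and KLRC1 had the lowest r (0.31). None of the 8 members passed when adjusted over the list alone, with a smallest adjusted p of 0.053. NCR1 was at a TPM of 0 in the 6 short-fragment biopsies, and KLRF1 reached a TPM of 1 only in long-fragment ones. Their pooled r thus in part restates the class. Given the class, r was 0.39 for KLRF1, 0.30 for NCR1, 0.28 for SH2D1B, 0.63 for KLRD1 and -0.18 for KLRC1. The T cell score had r = 0.48 (p = 0.139, adjusted p = 0.431; rho = 0.60, p = 0.057), with CD6 highest (0.66) and CD3G lowest (0.19). The B cell score had r = 0.37 (p = 0.261, adjusted p = 0.608; rho = 0.25, p = 0.471) and the cDC1 score r = 0.51 (p = 0.110, adjusted p = 0.413; rho = 0.59, p = 0.062). Without the 2 biopsies farthest from each score's median, r was 0.61 for NK cells (biopsies 5 and 8 left out, exact p = 0.079), 0.30 for T cells, 0.58 for B cells and 0.81 for cDC1 (biopsies 6 and 10 left out, exact p = 0.0095).

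Given the fragment length class, r was lower for 3 of these lists, at 0.44 for the NK cell score (permutation p = 0.178), 0.07 for T cells and -0.09 for cDC1, and was 0.31 for B cells, close to the pooled 0.37. Within the 6 short-fragment biopsies, r was 0.39 for NK cells (exact p = 0.453), 0.03 for T cells, 0.33 for B cells and -0.16 for cDC1. With the scores rescaled over those 6 biopsies, r for NK cells was -0.11, so its sign there depends on the scaling. No r was taken over the 5 long-fragment biopsies alone, since 6 was the smallest number used. With the read-through genes added to FLT3LG, r with the NK cell score was 0.52, and with TMM log2 CPM in place of TPM it was 0.38.

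**Figure D4:**
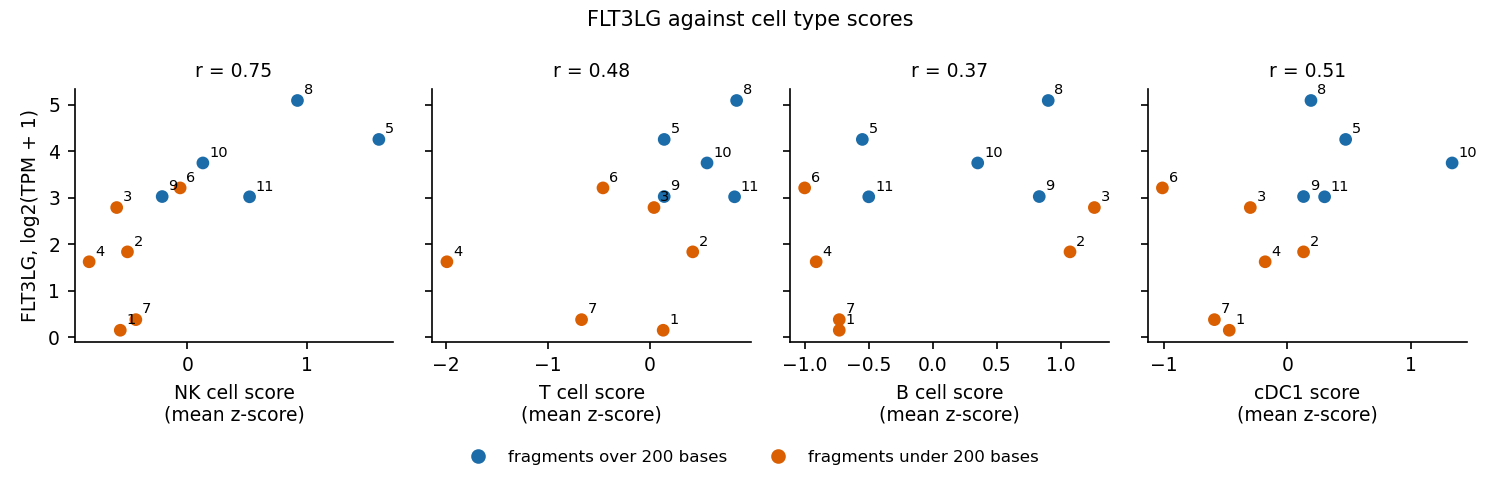
FLT3LG as log2(TPM + 1) (vertical axis) against the NK cell, T cell, B cell and cDC1 scores (horizontal axes, mean z-score), one numbered point per biopsy, colored by fragment length class. Pooled r is 0.75, 0.48, 0.37 and 0.51, and in the NK cell panel the 6 short-fragment biopsies lie below a score of 0 and the long-fragment ones, except biopsy 9, above it.

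The 28 list scores were each set against FLT3LG, and 0 passed the adjusted threshold, by Pearson r or by rank. Apart from the 4 lists above, the highest were housekeeping (r = 0.66, p = 0.025, adjusted p = 0.282; RPLP0, a ribosomal protein gene, r = 0.81), regulatory T cell (0.64, p = 0.034, adjusted p = 0.282; TNFRSF18 highest at 0.72, CTLA4 lowest at 0.39), keratinocyte (0.61, 2 detected genes), mast cell (0.60, 3 detected genes), mature dendritic cell (0.55, 3 detected genes), checkpoint receptor and ligand (0.50) and plasma cell (0.44). For the mast cell score, r was -0.24 without biopsies 5 and 8, 0.36 given the class and -0.49 within the 6 short-fragment biopsies. Values between 0.15 and 0.40 came from fibroblast (0.37), proliferation (0.28), plasmacytoid dendritic cell (0.27), interferon gamma response (0.26), stress and dissociation (0.26), CD8 T cell (0.25), antigen presentation class II (0.22), cDC2 (0.21), erythroid (0.20), cytotoxic effector (0.19), hypoxia and glycolysis (0.17) and endothelial (0.17, 2 detected genes). The lowest were macrophage and monocyte (0.12), dedifferentiated melanoma (0.09), neutrophil (0.09), hepatocyte (-0.08, 1 detected gene) and melanocyte lineage (-0.12). Given the fragment length class, r was 0.24 for housekeeping, 0.07 for regulatory T cells, -0.49 for macrophages and monocytes and 0.62 for stress and dissociation (adjusted p = 0.404). The lowest given the class were hepatocyte (-0.75, 1 detected gene, adjusted p = 0.261), endothelial (-0.67, 2 detected genes, adjusted p = 0.403) and hypoxia and glycolysis (-0.59, adjusted p = 0.404). Cytotoxic effector had -0.48. RPLP0 passed when its permutation test was adjusted over the housekeeping list alone (adjusted p = 0.0050), and given the class its r was 0.74 (permutation p = 0.0058). Another member of that list also passed in this way (adjusted p = 0.029), as did KRT5 over the keratinocyte list (adjusted p = 0.027). Adjusted over the genes of all lists, RPLP0 did not pass (adjusted p = 0.108), nor did it in the edgeR scan (adjusted p = 0.882). Its TPM ran from 0.82 to 657.

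**Figure D5:**
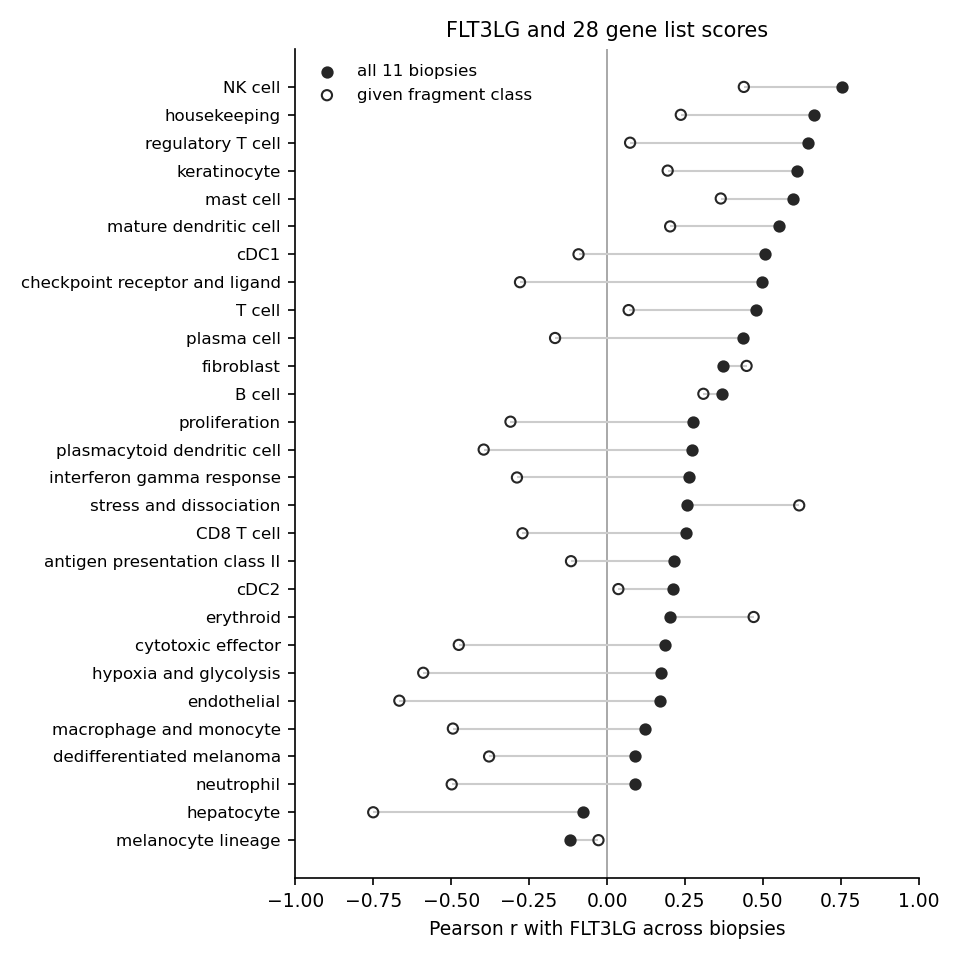
Pearson r between FLT3LG and each of 28 list scores over 11 biopsies (filled) and given the fragment length class (open). The NK cell list has the highest pooled r (0.75), which is 0.44 given the class.

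Whether NK cells were a closer partner of FLT3LG than other cells was tested on the difference of r. The NK cell score exceeded the T cell score by 0.28 (exact p = 0.138), the B cell score by 0.39 (exact p = 0.117) and the macrophage and monocyte score by 0.63 (exact p = 0.039, adjusted over the 3 differences 0.117). None passed the adjusted threshold. With 1 biopsy left out, these differences fell as far as 0.16 (without biopsy 1), 0.26 (without biopsy 2) and 0.42 (without biopsy 8). The difference against macrophages and monocytes was 0.93 given the fragment length class and did pass (adjusted p = 0.0352), with r of 0.44 and -0.49 for the 2 scores. Given the B cell score, the partial r of FLT3LG with the NK cell score was 0.82 (permutation p = 0.00097), and given the T cell score it was 0.67 (permutation p = 0.021). In the other direction, given the NK cell score, it was 0.60 with the B cell score (permutation p = 0.056) and 0.16 with the T cell score (permutation p = 0.657). None of these partial r values was adjusted for the fragment length class. With the read-through genes added, the differences against T cells and B cells were -0.15 and -0.02.

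The cDC1 score, built from genes of the dendritic cells that present antigen to CD8 T cells but also of other cells, passed the threshold with 1 of 27 lists, the plasma cell list (r = 0.87, permutation p = 0.00094, adjusted p = 0.025; rho = 0.78, adjusted p = 0.057). By rank the list that passed was housekeeping (rho = 0.92, adjusted p = 0.0043; r = 0.72, adjusted p = 0.129). Without biopsies 6 and 10 the r with the plasma cell score was 0.58 (exact p = 0.101, n = 9), so its size rests in part on those biopsies. It was 0.83 without biopsy 6 (adjusted p = 0.148) and 0.74 without biopsy 10 (adjusted p = 0.201). The call was also lost, with r at 0.86 or 0.87, without biopsy 1 (adjusted p = 0.0883), 3 (0.0651) or 11 (0.0537). Given the fragment length class it was 0.73 (p = 0.011), which does not pass over the 27 lists (adjusted p = 0.292), and given the number of detected genes it was 0.83 (p = 0.0014). For housekeeping, r given the class was 0.35. The score had r = 0.44 with the NK cell score (adjusted p = 0.324), 0.48 with T cells (adjusted p = 0.287) and 0.37 with B cells (adjusted p = 0.359). Given the class, these were -0.28, 0.07 and 0.32. Within the 6 short-fragment biopsies, r with the NK cell score was -0.74 (exact p = 0.093). Against 5 library measures, a comparison added after the data were examined, 4 passed with the cDC1 score (adjusted p = 0.025 each): the number of detected genes (r = 0.74, rho = 0.84), the mitochondrial share of counts (r = -0.72, rho = -0.94), the share of the 50 most abundant genes (r = -0.70, rho = -0.80) and mean fragment length (r = 0.66; rho = 0.52, adjusted p = 0.135). Without the 2 biopsies farthest from each measure's median, r was 0.64 (exact p = 0.056), -0.70 (exact p = 0.033), -0.50 (exact p = 0.173) and 0.77 (exact p = 0.012). The relations with detected genes and with the 50 most abundant genes thus no longer had a p under 0.05.

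Of 16 growth factors and chemokines, IL3 had no counts that varied and 0 of the other 15 passed with the cDC1 score. TGFB1 was highest (r = 0.61, p = 0.045, adjusted p = 0.521), followed by XCL1 (0.52), a chemokine for the cDC1 receptor XCR1 that is nearly identical to XCL2 (0.37), and FLT3LG (0.51). IL34 was lowest at -0.32. This order was not stable. By rank IL7 was highest (rho = 0.72, adjusted p = 0.168), above TGFB1 (0.69). Without the 2 biopsies farthest from each gene's median, r was 0.78 for XCL2 (exact p = 0.0026), 0.73 for KITLG (exact p = 0.040) and 0.69 for IL15 (exact p = 0.034), all unadjusted. For TGFB1 it was then 0.68 (exact p = 0.047), for XCL1 0.45 and for FLT3LG 0.32. Given the class, TGFB1 had 0.13, XCL1 -0.03, FLT3LG -0.09, XCL2 -0.18, KITLG 0.07 and IL15 0.37. Within the 6 short-fragment biopsies, r was -0.76 for XCL2 (exact p = 0.167), -0.07 for KITLG and 0.60 for IL15.

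No gene passed the threshold for an association with FLT3LG in the scan of 17144 genes with edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 668 positive and 363 negative genes, and the smallest adjusted p was 0.588. That balance depended on the setting, with 428 positive and 718 negative given the fragment length class, 383 and 1862 given the number of detected genes, and 2529 and 41 with limma. DESeq2 called 85 positive and 12 negative genes, limma on log2(TPM + 1) called 0, and edgeR without a filter on low counts called 657 and 306. All 8 NK cell list genes had positive slopes, as did 57.4% of all genes (list median log2 change 0.98 per SD of FLT3LG; camera adjusted p = 0.234). With the fragment length class as a further covariate, 4 of the 8 did, with a median of 0.485 (camera adjusted p = 0.366). In camera, 1 of 27 lists passed: the melanocyte lineage genes had a median log2 change of -1.53 per SD, with 2 of 10 slopes positive (adjusted p = 0.0215). That call was lost with an estimated correlation (adjusted p = 0.914), and given the fragment length class the list's direction turned upward (adjusted p = 0.774), while its median stayed at -0.90. Given the class, camera called the cytotoxic effector list downward and the stress and dissociation list upward (adjusted p = 0.0306 each, 0.81 with an estimated correlation).

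FLT3LG was also set against library measures. Its r was 0.48 with the total count, 0.59 with the number of detected genes, -0.43 with the share of the 50 most abundant genes and -0.45 with the mitochondrial share, and 0 of 4 passed (adjusted p from 0.153 to 0.182 over 5 measures). Without the 2 biopsies farthest from each measure's median, r was 0.60 (exact p = 0.078), 0.86 (exact p = 0.0031), -0.43 (exact p = 0.244) and -0.54 (exact p = 0.135). Mean fragment length, added after the data were examined, had r = 0.68 (p = 0.025, adjusted p = 0.124), and 0.59 without the 2 farthest biopsies (exact p = 0.101). The NK cell score, a comparison also added then, had r = 0.70 with the number of detected genes and 0.69 with fragment length (adjusted p = 0.038 each), but neither passed by rank (rho = 0.71 and 0.70, adjusted p = 0.0512 each). The T cell score passed by rank alone, with the mitochondrial share (rho = -0.83, adjusted p = 0.0141) and the share of the 50 most abundant genes (rho = -0.74, adjusted p = 0.0326; r = -0.49 and -0.46, adjusted p = 0.242 each).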

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

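Reads assigned to read-through genes lie outside the main measurement of FLT3LG, and there they exceeded the 3 counts that a count of 0 allows. The FLT3LG-RPL13A read-through gene (ENSG00000273189, chromosome 19, 49474586 to 49487637) had 433 expected counts in biopsy 2, against 21 for FLT3LG itself, and at most 11 in any other biopsy. The ALDH16A1-FLT3LG read-through gene (ENSG00000269469, chromosome 19, 49462752 to 49486231) had 21 expected counts in biopsy 1, against 1 for FLT3LG, and 0 in the others. The first also overlaps RPL13A and the second ALDH16A1. Counts rest on single biopsies, and which gene or transcript the reads came from was not tested.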

How the results depend on the processing

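Settings that involve the fragment length class, the number of detected genes, the mitochondrial share, nuclear TPM or the read-through genes were chosen after seeing the data. The count of 0 lists passing with FLT3LG, adjusted over all lists, and of 0 cytokines passing with the cDC1 score held under every setting run, while over the 4 main lists alone the NK cell list passed (adjusted p = 0.029), and r of FLT3LG with the NK cell score ranged from 0.69 (without biopsy 8) to 0.79 (without biopsy 3) with 1 biopsy left out. Where a direction or call changed, the cause was not tested, except that settings with fewer biopsies have less power by construction. The count of 1 list passing with the cDC1 score was 2 with a pseudocount of 0.1 and given PTPRC; it was 0 given the fragment class, in the short-fragment biopsies (rescaled or not), without the 2 highest mitochondrial shares and with nuclear TPM. With 1 biopsy left out it ran from 0 (without biopsy 1, 3, 6 or 11) to 3 (without biopsy 2), and was 2 without biopsy 4; without biopsy 10 the list that passed was housekeeping, and the plasma cell r was 0.74 (adjusted p = 0.201). The r of FLT3LG with the melanocyte lineage score (-0.12) turned to 0.01 with a pseudocount of 0.1, 0.05 with TMM log2 CPM, 0.16 by rank, 0.21 given PTPRC and 0.16 in the short-fragment biopsies (rescaled or not), and ran from -0.37 to 0.03 with 1 biopsy left out. With the macrophage and monocyte score (0.12) it was -0.25 by rank, -0.49 given the fragment class, -0.65 in the short-fragment biopsies (-0.28 rescaled), -0.15 given genes detected, -0.08 with the read-through genes added, -0.10 without the 2 farthest biopsies and from 0.04 (without biopsy 1) to 0.28 (without biopsy 8) with 1 biopsy left out. Given the fragment class, r was -0.09 for FLT3LG with the cDC1 score, -0.28 for the cDC1 score with the NK cell score and -0.03 with XCL1; given genes detected the last 2 were -0.15 and -0.01. In the short-fragment biopsies, FLT3LG had -0.08 with regulatory T cells and -0.16 with cDC1, and the cDC1 score had -0.74 with NK cells and -0.41 with XCL1. With scores rescaled over those 6 biopsies, FLT3LG had -0.11 with NK cells, -0.24 with regulatory T cells and -0.13 with cDC1, the cDC1 score had -0.67 with NK cells, -0.39 with T cells, -0.40 with XCL1 and -0.26 with TGFB1, and the NK cell differences were -0.14 against T cells and -0.44 against B cells. With the read-through genes added, those differences were -0.15 and -0.02; given the fragment class, the difference against macrophages and monocytes was 0.93 and passed the threshold (adjusted p = 0.0352). The scan's 0 positive and 0 negative genes became 85 and 12 with DESeq2 and 657 and 306 without a filter, and stayed 0 with each biopsy left out. In camera, 1 list passed, 0 with an estimated correlation and 2 given the fragment class. Counting error is large for FLT3LG in biopsies 1 and 7, at 1 and 5 expected counts.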

Other observations

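All tests here were chosen after the data were examined, except that 3 of the explanations below had their bounds written before their results were seen: random lists, mitochondrial transcripts and loss of rare transcripts. Across all 378 pairs of list scores, 9 passed an adjusted p of 0.05, all with positive r. Given the fragment length class 4 pairs passed, 3 of them among the 9, and by rank 7 passed, 4 of them among the 9. The CD8 T cell score went with the interferon gamma response score (r = 0.93, adjusted p = 0.018; given the fragment length class 0.89, adjusted p = 0.038; 0.94 in the 6 short-fragment biopsies, exact p = 0.0069), and with the cytotoxic effector score (r = 0.90, adjusted p = 0.018; 0.85 given the class, adjusted p = 0.109) and the checkpoint receptor and ligand score (r = 0.88, adjusted p = 0.032; 0.89 given the class, adjusted p = 0.038; by rank adjusted p = 0.0997). The lists share no gene. GBP5, an interferon-induced GTPase, was 1115 in biopsy 1 and 713 in biopsy 11, where CD8A was 544 and 655. The proliferation score went with hypoxia and glycolysis (r = 0.87, adjusted p = 0.032; 0.78 given the class, adjusted p = 0.159; by rank adjusted p = 0.099), and the macrophage and monocyte score with the endothelial score (r = 0.77, adjusted p = 0.047; 0.65 given the class, adjusted p = 0.309; by rank adjusted p = 0.138), which fell to 0.41 without the 2 farthest biopsies. The endothelial score rests on 2 detected genes of its 6, PECAM1, which leukocytes also express, and VWF, at a TPM of 8.63 in biopsy 9 and at most 1.49 in the others.

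Hypotheses on the mixture of cells were set against these values. Interferon gamma response genes may follow cytotoxic lymphocytes: r with the cytotoxic effector score was 0.88 (adjusted p = 0.028), and 0.82 given the class, which does not pass (adjusted p = 0.119). Tumor cells and T cells may take complementary shares of the sorted cells: r between the melanocyte lineage and T cell scores was -0.76 (adjusted p = 0.135), -0.86 given the class (adjusted p = 0.038), but rho was -0.43 and r was -0.49 without biopsies 4 and 7. HSPA1A and HSPA1B, heat shock genes that are near copies of each other, may go with tumor cells: r with the melanocyte lineage score was 0.63 (p = 0.041), and rho 0.39 (p = 0.237), so the relation is not kept by rank.

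The relation of FLT3LG with the NK cell score was set against technical causes. Random lists of the same size and mean expression had a median r of 0.52 with FLT3LG. The NK cell list lay at percentile 98.0 of 10000, past the bound written beforehand. With 1 biopsy left out, a check added afterwards, it lay from 85.5 (without biopsy 6) to 99.5. The random lists were not matched on how closely members vary together (estimated inter-gene correlation 0.318 for the NK cell list). Other lists lay at the low end (melanocyte lineage at percentile 0, macrophage and monocyte at 0.14). The NK cell list had the highest r of all lists, and its percentile does not allow for that choice. Shared library complexity thus cannot be told apart from the pattern by these percentiles or by those given the class. Given PTPRC, r stayed at 0.73, so the level of this transcript did not account for the relation. PTPRC is a single marker that need not measure the share of leukocytes, so this value cannot decide on total leukocyte content. Given the fragment length class r was 0.44, against a median of -0.08 for the random lists (percentile 98.53, and 83.7 without biopsy 6), but 3 other lists had a higher r given the class, stress and dissociation (0.62, percentile 99.46), erythroid (0.47, 95.68) and fibroblast (0.45, 98.29). A permutation p of 0.178 over the biopsies leaves open how much of the relation comes from the class. Adding the read-through genes gave 0.52, so the relation depends on which gene those reads came from. Apart from the level of PTPRC, nothing that bears on a biological explanation of this relation was tested.

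The short-fragment libraries detected fewer genes. The ratio of their mean total count to that of the long-fragment libraries was 1.004, but their mean nuclear count was lower (12491000 against 16199000), so depth is matched by thinning alone. After mitochondrial counts were left out and every library was thinned to 4743522 nuclear counts, the long-fragment libraries still had 5763 more genes with at least 5 counts (exact permutation p = 0.0065), which argues against sequencing depth and against mitochondrial transcripts as the whole cause. Of the 1000 most abundant genes of the long-fragment libraries, a mean of 10.8 had no count in a short-fragment library (2 to 41) and 0.2 in a long-fragment one (exact permutation p = 0.056), and of the 1000 ranked in the short-fragment libraries themselves 19.7 and 3.2 (exact permutation p = 0.054). Every short-fragment library lacked at least 2 of the first 1000, and no long-fragment one lacked more than 1. The first 1000 were ranked in the long-fragment libraries, so their presence there follows in part from that choice. Genes without a count were taken from the full counts, so these numbers are not matched for depth. For the second 1000 the ranges overlapped (1 to 51 in the short-fragment and 1 to 6 in the long-fragment libraries). Neither difference passed 0.05, a threshold that the bound written beforehand did not include. A loss of transcripts from few starting molecules may contribute. Different cell mixtures could also leave such genes without a count, and no test separated these explanations. No biological explanation was tested.

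With limma, 86.4% of 17144 slopes on FLT3LG were positive and 2529 positive genes had an unadjusted p under 0.05. Over 100 permutations of FLT3LG across biopsies, as many genes passed in either direction in 5 and were positive in 3. The positive count had a median of 195.5 and a highest value of 4158.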
